A study of Homo sapiens with 8 samples.

How the data were processed

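Gene expression was measured in 8 samples of MRC5 and IMR90, established lines of human lung fibroblasts. Per the labels' protocols, the cells received a lentivirus set for Oct4, Sox2, Lin28 and Nanog together with a retrovirus that was either empty (EV) or over-expressed HIF2α (HIF2A), and were grown in medium for human embryonic stem cells. Samples were labelled as day 12 or day 30. The groups were EV day 12, HIF2A day 12, EV day 30 and HIF2A day 30, each with 1 MRC5 and 1 IMR90 sample. For the IMR90 EV day 12 sample the description gives a slightly different day from the title and the characteristics, and the latter were used.

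Per the labels' protocols, RNA was taken from the adherent cells and 200 ng per sample was labelled with Cy3 or Cy5. The 4 arrays were Agilent arrays with 60-base probes in 2 colours, on 1 slide read in 1 scan. Each array held 1 group, with MRC5 in Cy3 and IMR90 in Cy5, and dyes were not swapped. Within a day the virus cannot be told apart from the array, and the cell line cannot be told apart from the dye anywhere. The files of both dyes of an array were identical in all 4 cases, and the channel named by each sample's label was used.

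Per the file headers, Feature Extraction 10.7.3.1 read each spot, and the deposited mean and background signals are intensities on a linear scale with no normalization. Per the file headers, its processed signals, also intensities, were background subtracted, detrended and normalized between dyes. The authors also deposited 1 table of log2 values over all 8 samples. The submitters' processing notes name Feature Extraction and the affy package without saying what each did, so the background step behind that log2 table is not given in the sources used here. Its columns have medians of 6.14 to 6.15, and each column correlated with the processed signal of the sample it names at a Spearman rho of at least 0.99999. Of its 43376 lines, 31731 carried a probe name, and 29409 probes could be matched. It was used only as an alternative.

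From the mean and background median signals, the background was corrected with normexp (offset 50), each array was normalized by loess with control spots at weight 0, and the arrays were aligned with Aquantile, all in limma 3.58.1 under R 4.3.3 with statmod 1.5.0 and the package data.table (version 1.17.8). The 2 channels were then treated as separate samples on the log2 scale. Each array had 45015 spots, of which 1639 were controls and were left out, as were spots marked as outliers. Spots of a probe were averaged. Probes that lay well above background in at least 2 of the 8 samples were kept, 29827 of 41000, and each gene was represented by its brightest probe by mean log2 over all samples, giving 22121 genes. Of these genes, 5777 had several probes kept, and for genes past the threshold the other probes were compared with the one used.

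The array's gene names were updated through reference tables of RefSeq accessions and symbols. Of the probes, 26222 matched by accession, 1646 by symbol and 466 by an older symbol, and the other 12666 kept the name in the file. Among the genes tested, 15104 had a current symbol. Probes for XIST and Y-linked genes, 146 in all, were left out of every step. Positions are on hg19, as the array annotation gives them, and no genome sequence was used here.

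Genes were tested with limma's lmFit and eBayes and called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons within a day, between days and of the virus effect between days used 1 fit of the 4 groups with the cell line as a block, which left 3 residual degrees of freedom. The comparison of virus over both days used an additive fit of line, day and virus with the array as a random block, whose estimated correlation within arrays was -0.022, with 4 residual degrees of freedom. The cell line by virus term left 2. Pairing comes from the design, since both samples of a group differ in cell line and each line appears in every group. The differences between the lines correlated between groups at -0.384 to 0.391 over genes.

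The 18 gene lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry, adjusted over the lists within a comparison. KDM4B, NDUFA4L2 and TDGF1 were list members that matched no probe by name, and whether the array holds them under other names was not checked. A list needed at least 5 tested members, and the smallest lists had 6. The lists, the comparisons, the threshold, the named-gene rule and most alternatives were choices made before the data were examined. In the comparisons of virus at each day, of virus over both days and of day with EV, the rule named the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with the same sign in both lines and a current symbol. Where fewer passed, it added genes with the largest smaller change of both lines, given as values that did not pass. In the other comparisons it named 5 and 5, within lists up to 4 members past the threshold or else 2, and in every comparison EPAS1, HIF1A, TNFSF10, POU5F1, SOX2, NANOG and LIN28A. Where both samples of a group were not well above background, the fold is given as "at least", from the brighter group's mean against the higher of the dim probe's own value and the lowest value among probes well above background.

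The fits were tested on simulated log2 values of 22121 genes, of which 200 changed, 50 at each size. The simulated noise was independent, with no array or line effect and no correlation between genes or within arrays. Background correction, normalization, the filter and the choice of probes were not part of it. The shares and false calls therefore hold only for that simpler setting. For HIF2A against EV at day 12, 0% of genes changed by 1 on the log2 scale were recovered, 32% of those changed by 2, 68% of those changed by 4 and 84% of those changed by 6, with 5 false calls. At day 30 these shares were 2%, 24%, 72% and 84%, with 5 false calls. For HIF2A against EV over both days they were 22%, 72%, 90% and 96%, with 5 false calls, and for IMR90 against MRC5 they were 4%, 52%, 86% and 90%, with 8.

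Alternatives changed 1 step each, except that the processed signals and the authors' log2 table replaced background correction and normalization together, and that table also changed the genes tested (16275). They were no background correction, quantile normalization over the 8 channels, the processed signals, the authors' log2 table, no filter on dim probes, a filter on all 8 samples, the mean of a gene's probes, eBayes with trend and robust, no cell line block, the array as a random block or not, and each sample left out in turn. A further exception was the comparison over both days. There the correlation within arrays was estimated anew in each fit without 1 sample and wherever the signals, the filter, the probe summary or the cell line block changed. With all samples entered, these settings gave -0.135 to -0.019, against -0.022, so their counts over both days hold both changes. Another probe of EPAS1 and leaving out both samples least like the others were added after the data had been seen. The precision is limited by the number of arrays and by signal over background, whose median per sample lay between 2.12 and 4.01.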

Results

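Fibroblasts of the lines MRC5 and IMR90 were carried towards pluripotency with viruses for Oct4, Sox2, Lin28 and Nanog, in the presence of an empty vector (EV) or of HIF2α (HIF2A), a transcription factor that is stabilised in low oxygen and is encoded by EPAS1. Transcript levels at day 12 and day 30 were read on 4 arrays, with 2 samples per group, 1 of each line. Each line gave 1 sample per group, and the labels name no repeat culture of a line. No p-value therefore measures a spread between repeat cultures. In the fit of the 4 groups, p-values rest on how the difference between the lines varied from group to group. That variation holds culture and technique as well as the lines' responses. A constant line difference is taken out there. Spread between arrays is not measured, since each group was 1 array. Over both days, the difference of the virus effect between days enters too. It holds spread between arrays and any real change of the effect with day, which cannot be told apart. The share of spots well above background ran from 55.7% in MRC5 EV day 12 to 73.8% in IMR90 EV day 30, and 0 spots were saturated. Over genes, the 2 samples of a group correlated at r = 0.978 for EV day 12, 0.938 for HIF2A day 12, 0.944 for EV day 30 and 0.994 for HIF2A day 30. MRC5 HIF2A day 12 and IMR90 EV day 30 were least like the others, with a mean r of 0.913 and 0.897. Changes are differences of log2 intensity ± SE from limma, each n is 2 per group unless stated, and p-values are adjusted by Benjamini-Hochberg.

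EPAS1 itself was read by 2 probes that moved apart. The brighter probe, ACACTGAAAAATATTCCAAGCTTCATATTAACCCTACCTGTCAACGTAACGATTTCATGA, lies on chromosome 2 from 46613666 to 46613725 of hg19, at the 3′ end of the gene, which is untranslated by general knowledge of EPAS1. Its log2 level at day 12 was 12.62 in MRC5 EV, 14.68 in IMR90 EV, 12.18 in MRC5 HIF2A and 12.44 in IMR90 HIF2A, and at day 30 it was 15.11, 13.32, 12.37 and 12.51 in the same order. The fitted EPAS1 difference, HIF2A minus EV, was -1.35 ± 0.89 at day 12 (adjusted p = 0.669) and -1.78 ± 0.89 at day 30 (adjusted p = 0.441). With 1 sample left out it ran from -2.60 to -0.09 at day 12, the ends without MRC5 and without IMR90 EV day 12, and from -3.08 to -0.48 at day 30, the ends without IMR90 and without MRC5 EV day 30. A probe at the 3′ end checks no label where the delivered cDNA lacks that part. The dimmer probe, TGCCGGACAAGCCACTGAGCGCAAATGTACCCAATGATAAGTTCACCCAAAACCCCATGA, has no position in the array annotation and was placed in the coding sequence by general knowledge of the protein alone. By that probe the samples labelled HIF2A were higher than EV by 1.56 in MRC5 and 0.96 in IMR90 at day 12 and by 0.88 in IMR90 at day 30. The difference was -0.71 in MRC5 at day 30, opposite to the label when taken alone. The 3′ probe fell by more there (-2.74), and the coding probe may read the cells' own EPAS1 too. The value of -0.71 therefore cannot decide the label. Neither day passed with the coding probe, at 1.26 ± 0.75 for day 12 (adjusted p = 0.687) and 0.09 ± 0.75 for day 30 (adjusted p = 0.977).

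**Figure D1:**
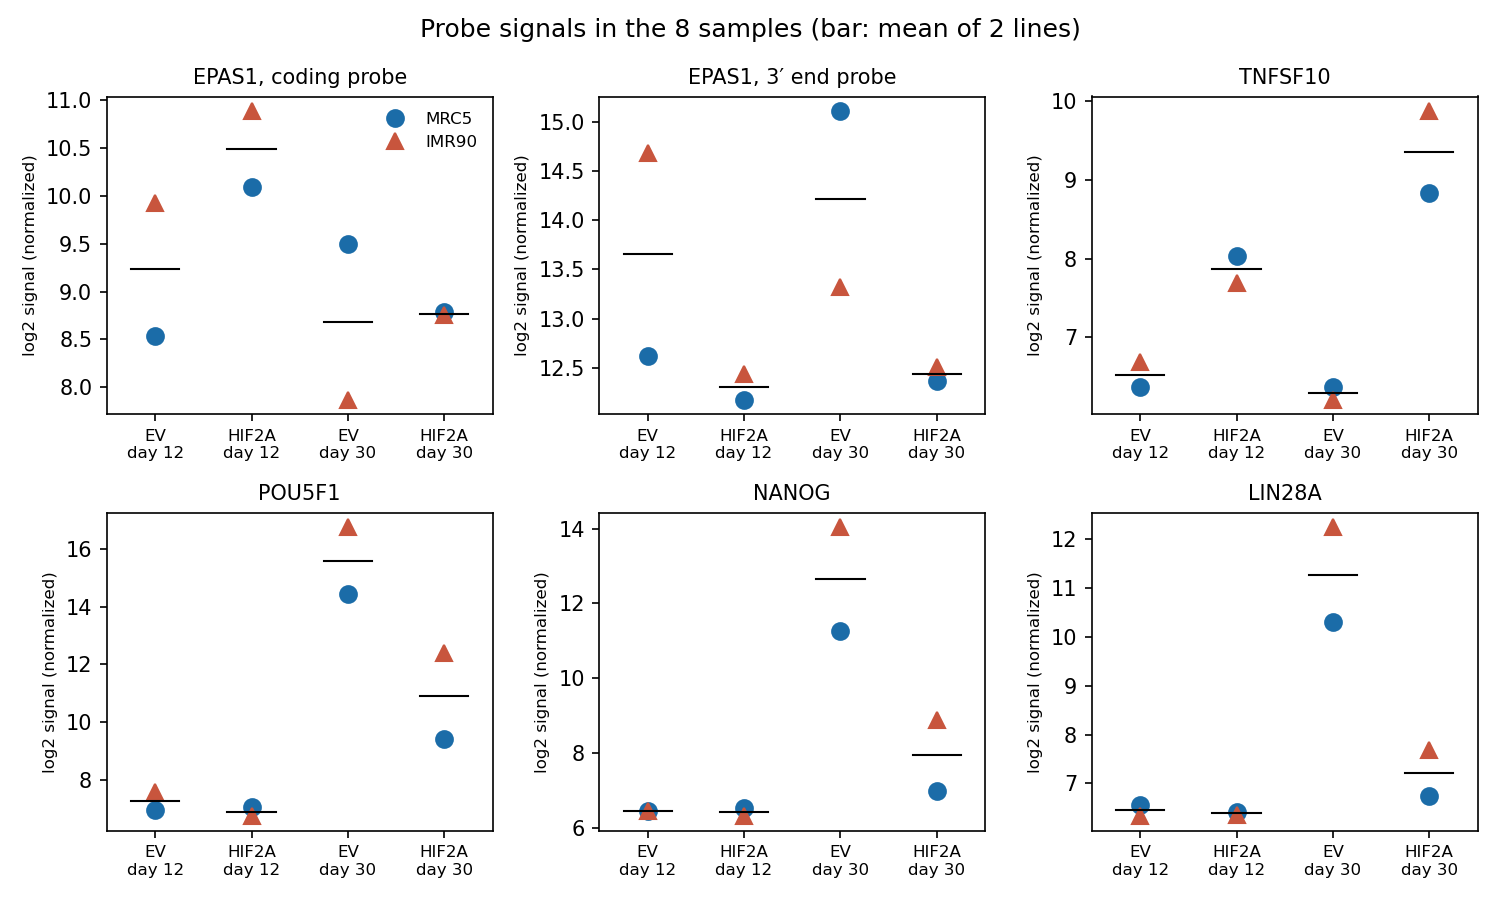
Log2 intensity of each sample (points, 1 per cell line) in the 4 groups, with bars at the mean of both lines, for both EPAS1 probes, TNFSF10, POU5F1, NANOG and LIN28A. TNFSF10 was higher in the samples labelled HIF2A in both lines at both days, while POU5F1, NANOG and LIN28A were high in EV at day 30 and lower in the samples labelled HIF2A.

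The comparison of HIF2A with EV at day 12 asked which transcripts differ at the early stage. By the naming rule, the difference was 8.42 ± 0.73 for NPPB, a natriuretic peptide, 7.25 ± 0.46 for IGFBP3, a binder of insulin-like growth factors, and 7.01 ± 0.37 for INHBB, an activin subunit. PTGIS, the prostacyclin synthase, differed by 6.16, with 5.91 for EGLN3, a prolyl hydroxylase that marks HIF for decay, and 5.14 for NDRG1. Values were 4.78 for ERRFI1, a brake on EGF receptors, 4.64 for ZNF395 and 4.60 for AK4, a mitochondrial adenylate kinase. CXCR4, a chemokine receptor, was not well above background in EV and was at least 25.1-fold higher (fitted difference 4.73). Differences in the other direction were -3.55 for the homeobox gene IRX3, -3.50 for PSORS1C2, and -3.44 for KLK3. Next came -3.13 for ASS1, the argininosuccinate synthase, -3.08 for FRMD4A and -2.69 for the T-box gene TBX2. The others were -2.46 for GSG1, -2.29 for CASP8, the initiator caspase of death receptors, -2.20 for the chromatin protein HMGA1 and -1.97 for PAPPA, a protease of IGF-binding proteins. By limma, 0 of 22121 genes passed, with a smallest adjusted p of 0.0534 for INHBB, CXCR4 and the desmosome gene DSP (3.60). In EV, 1 of the 2 samples was well above background for INHBB, PTGIS, EGLN3 and TNFSF10, and in each group 1 of 2 for NANOG. At an unadjusted p under 0.05 there were 1665 genes, where chance gives 1106. TNFSF10, which codes for the death ligand TRAIL, differed by 1.34 ± 0.38 (adjusted p = 0.619). HIF1A differed by -0.08, POU5F1 by -0.37, SOX2 by -0.46, NANOG by -0.02 and LIN28A, not well above background in EV, by -0.06. Each of these 5 had opposite signs in the 2 lines.

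As a group, the HIF target genes rose at day 12 in the samples labelled HIF2A, with a median of 1.16, 34 of 35 members above 0 and 27 above 0 in both lines (camera, adjusted p = 6.27e-20). The adjusted p = 0.316 with an estimated correlation, and fry gave 0.0384. Of the 45 list calls in all comparisons fry kept 5, the HIF targets at day 12 and over both days and 3 lists of day with EV, and camera with an estimated correlation kept 0. No HIF target passed over all genes, and 16 were higher when adjusted over the list alone. The unfolded protein response list rose too, with a median of 0.56 and HSP90B1, a chaperone, at 1.73 (adjusted p = 0.0139; adjusted p = 0.562 with an estimated correlation). Of its 16 members 0 passed over all genes or adjusted over the list alone. Its call was lost without IMR90 HIF2A day 12 (median 0.80, adjusted p = 0.0815), with the processed signals and the authors' log2 table (0.74 each, adjusted p = 0.0562 and 0.0664) and with the mean of a gene's probes (0.32, adjusted p = 0.0532), and its median was 0.22 without MRC5 HIF2A day 12. The glycolysis list had a median of 0.14 with LDHA, lactate dehydrogenase, at 2.18 (adjusted p = 0.0949), and the death receptor list, which holds TNFSF10 and CASP8, had a median of 0.23 (adjusted p = 0.248). Other settings called 94 genes from the processed signals, 87 from the authors' log2 table, 26 with trend and robust eBayes and 14 without the cell line block, and 0 to 7 in the rest.

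The comparison at day 30 addressed the late stage. The nodal antagonists LEFTY1 and LEFTY2 differed by -5.32 ± 0.41 and -5.10 ± 0.54. DPPA5, SALL4 and POU5F1, markers or regulators of embryonic stem cells, differed by -4.93, -4.54 and -4.68, and SEMA6A by -4.74. These 6 did not pass (adjusted p = 0.0537 to 0.14). Past the threshold, CST1, a cystatin, fell by 3.23 ± 0.19, GSC, a homeobox gene of the primitive streak, fell by 3.12 ± 0.20, and APOA2, an apolipoprotein, fell by 3.02 ± 0.17. For CST1, GSC, APOA2 and DPPA5, 1 of the 2 samples labelled HIF2A was well above background, and for PCSK6 1 of the 2 EV samples. S100A14 was not well above background with HIF2A, and EV lay at least 7.55-fold higher. In the other direction C5orf46 rose by 5.90 ± 0.33, PCSK6, a convertase of secreted proproteins, by 4.67 ± 0.18, and PTHLH, parathyroid hormone-like hormone, by 4.10 ± 0.23. PRSS35 rose by 3.56, SLC6A8, a creatine transporter, by 3.47, PLAC8 by 3.45, GALNT18 by 3.25 and STEAP3, a ferrireductase, by 2.85. TREM1, a receptor of myeloid cells, rose at least 6.69-fold and HHIP, an inhibitor of hedgehog signalling, at least 5.73-fold from EV levels that were not well above background. These genes and 1 unnamed probe made up the 15 of 22121 that passed in limma, 11 higher and 4 lower (adjusted p = 0.0412 or 0.0468), beside 3491 at an unadjusted p under 0.05. TNFSF10 was at least 8.38-fold higher (fitted difference 3.07 ± 0.38, adjusted p = 0.0833), from an EV level not well above background. Differences that did not pass were -3.46 for SOX2, -4.71 for NANOG, -4.05 for LIN28A and -0.92 for HIF1A (adjusted p = 0.0856 to 0.589). The NANOG probe and 3 of the 4 POU5F1 probes are annotated at other chromosomes than those genes, 15 and 12, where by general knowledge related pseudogenes lie. The viruses' own transcripts may add to probes within coding sequence.

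The pluripotency list fell at day 30, with a median of -1.99 and 29 of 31 members lower in both lines (camera, adjusted p = 7.59e-20; adjusted p = 0.347 with an estimated correlation). Over all genes 0 members passed, and 26 were lower when adjusted over the list alone. The reprogramming factors fell with it (median -3.76, adjusted p = 2.13e-06; adjusted p = 0.347 with an estimated correlation), 5 of 6 when adjusted over the list alone and 0 over all genes. Epithelial genes had a median of -1.06, with the tight junction gene CLDN6 at -3.82 and E-cadherin, CDH1, at -3.62 (adjusted p = 6.98e-08; adjusted p = 0.495 with an estimated correlation). Of these, 12 were lower and 1 higher when adjusted over the list alone and 0 over all genes. HIF target genes rose, with a median of 1.51, 29 of 35 higher in both lines, IGFBP3 at 6.12 and NDRG1 at 5.06 (adjusted p = 1.5e-11; adjusted p = 0.347 with an estimated correlation). Of these, 19 were higher when adjusted over the list alone and 0 over all genes. By fry no list passed at day 30, at 0.0569 for pluripotency, reprogramming factors and HIF targets and 0.123 for epithelial genes. The epithelial median was -2.21 without MRC5 EV day 30 and -0.58 without IMR90 EV day 30, its call kept.

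Cell cycle genes fell as a group at day 30, with a median of -1.23, 29 of 32 lower in both lines and the replication licensing gene MCM5 at -2.92 (camera, adjusted p = 4.12e-07; adjusted p = 0.495 with an estimated correlation). Fibroblast genes rose, with a median of 0.61 and S100A4 at 3.23 (adjusted p = 0.00163; adjusted p = 0.544 with an estimated correlation). So did p53 targets, with a median of 0.55 and ZMAT3 at 1.23 (adjusted p = 0.00266; adjusted p = 0.347 with an estimated correlation). Respiratory chain genes, with a median of -0.37 (adjusted p = 0.00533), and glycolysis genes, with a median of -0.49 and hexokinase 2, HK2, at -2.34 (adjusted p = 0.0287), were lower. Both had an adjusted p = 0.495 with an estimated correlation. By fry the 5 lists had 0.382, 0.57, 0.13, 0.261 and 0.319, in that order. In these 5 lists 0 members passed over all genes or when adjusted over the list alone. Without MRC5 EV day 30 the cell cycle and fibroblast medians were -2.49 and 1.22. Leaving out IMR90 EV day 30 ended all 5 calls, with medians of -0.09, -0.09, 0.32, -0.34 and -0.15, the fibroblast list turning sign. The glycolysis call also ended without MRC5 or IMR90 HIF2A day 12 (-0.49 each) or IMR90 HIF2A day 30 (-0.23) and in 3 other settings (-0.51 to -0.43, adjusted p = 0.0687 to 0.151). The respiratory call ended with the processed signals and the authors' log2 table (adjusted p = 0.193 and 0.257), its median staying at -0.38 and -0.37.

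The day 30 count rested on single samples and on the signal used. Without MRC5 EV day 30 the test called 632 genes, and without any 1 of the other 7 samples it called 0. In MRC5 the day 30 sample labelled HIF2A had less EPAS1 than EV by the coding probe (-0.71) and by the 3′ probe (-2.74). HIF targets there had a median of 1.24, in the direction of the label. TNFSF10 differed by 2.46, but its direction with HIF2A is known here only from these labelled samples, so it cannot bear on the label. The split of 11 higher to 4 lower became 57 to 70 without background correction, 20 to 15 with quantile normalization, 393 to 846 with the processed signals and 313 to 712 with the authors' log2 table. Without the cell line block 124 genes passed.

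**Figure D2:**
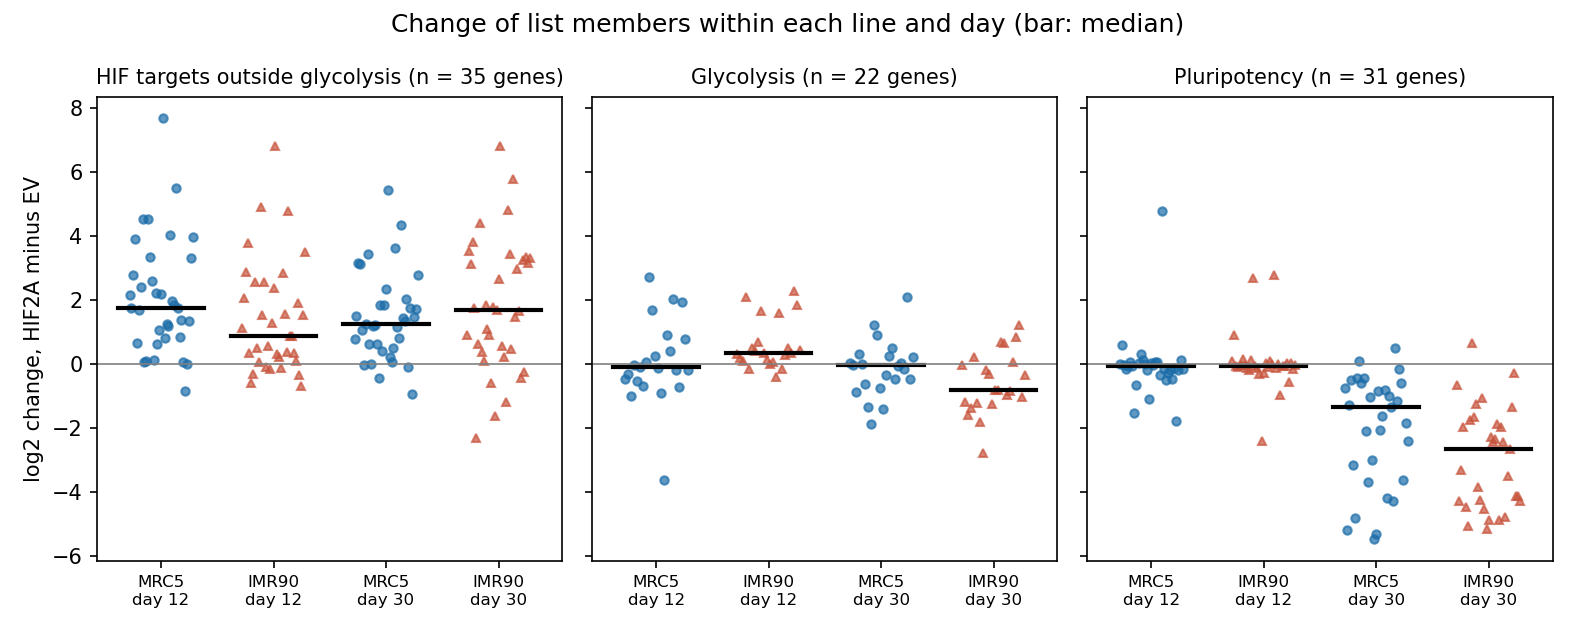
Log2 change, HIF2A minus EV by label, of each member of the HIF target, glycolysis and pluripotency lists, by cell line and day, with bars at the list median. HIF targets had fitted medians of 1.16 at day 12 and 1.51 at day 30, glycolysis genes 0.14 and -0.49, and pluripotency genes -0.06 and -1.99.

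Over both days, the samples labelled HIF2A were set against EV with 4 samples a side, and classic responders to low oxygen stood out. IGFBP3 rose by 6.69 ± 0.37, EGLN3 by 5.93 ± 0.33 and NDRG1 by 5.10 ± 0.30 (limma, adjusted p = 0.00958 each). INHBB rose by 5.84, PTGIS by 5.83, C5orf46 by 4.91 and APLN, the ligand of the apelin receptor, by 4.65. ZNF395 rose by 4.11, LOX, a crosslinker of collagen, by 3.82 and CA12, a carbonic anhydrase, by 3.73 (adjusted p = 0.014 to 0.0391). TBX2 fell by 2.90 ± 0.27 (adjusted p = 0.0388) and HMOX1, a haem oxygenase, fell by 2.06 ± 0.20 (adjusted p = 0.0399). In all 27 of 22121 genes passed, 25 higher and 2 lower, with 2974 at an unadjusted p under 0.05. Of the 27, 24 had a current symbol and the rest were unnamed probes. An unnamed probe that rose by 3.88 lies close to the probe of BHLHE40 (3.66) on chromosome 3, so 1 gene may be counted more than once. Differences that did not pass were -3.54 for LEFTY1, -3.03 for HMGA1, -3.05 for SEMA6A, and -2.61 for LEFTY2, then -2.54 for SMCR5, -2.52 for POU5F1, -2.46 for DRAXIN and -2.42 for DPPA5 (adjusted p = 0.136 to 0.407). TNFSF10, well above background in 1 of 4 EV samples, had a fitted difference of 2.20 ± 0.43 (adjusted p = 0.195) and was higher in 4 of 4 pairs. In EV, 3 of 4 samples were well above background for INHBB, PTGIS, EGLN3, LEFTY2 and NANOG and 2 of 4 for DPPA5 and LIN28A. With HIF2A they were 3 of 4 for NANOG and LIN28A, 2 of 4 for LEFTY2 and 1 of 4 for DPPA5. SOX2 differed by -1.96, NANOG by -2.37, LIN28A by -2.05, EPAS1 at its 3′ probe by -1.56 and HIF1A by -0.50 (adjusted p = 0.315 to 0.641). Leaving out 1 sample, with the correlation within arrays estimated anew, moved many of these. The range was -3.66 to -0.77 for NANOG, -3.15 to -0.71 for LIN28A and -3.78 to -0.72 for DPPA5, lowest without IMR90 EV day 12 and highest without IMR90 EV day 30 or, for DPPA5, MRC5 HIF2A day 30. It was -0.98 to -0.06 for HIF1A, its ends without MRC5 and without IMR90 HIF2A day 12. Without MRC5 HIF2A day 30 POU5F1 came to -0.97, LEFTY2 to -0.91, SOX2 to -1.01 and SEMA6A to -1.84. SMCR5 came to -1.51 without IMR90 EV day 30, and EPAS1 to -0.97 without MRC5 EV day 30.

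HIF target genes rose as a group over both days, with a median of 1.47 and 29 of 35 higher in both lines (camera, adjusted p = 2e-20; adjusted p = 0.089 with an estimated correlation; fry 0.00296). Of them 8 passed over all genes, among them IGFBP3, NDRG1, LOX and CA12, and 24 were higher when adjusted over the list alone. The glycolysis list, by contrast, had a median of -0.07 with the glucose transporter SLC2A1 at 1.88 (adjusted p = 0.757 for the list), and a median of 0.03 with the authors' log2 table. Of its members 0 passed over all genes and 1 when adjusted over the list alone. Within the HIF pathway list EGLN3 was the 1 member that passed, over all genes and when adjusted over the list alone. The list's median of -0.30 and camera's direction differed in sign from its mean of 0.25 (adjusted p = 0.844). Pluripotency genes fell, with a median of -0.95 (adjusted p = 1.29e-08; adjusted p = 0.758 with an estimated correlation). Reprogramming factors fell, with a median of -2.01 (adjusted p = 0.00861; adjusted p = 0.758 with an estimated correlation). By fry both had 0.327. In both lists 0 members passed over all genes or when adjusted over the list alone. Their medians were -0.06 and -0.09 at day 12 (camera, adjusted p = 0.666 and 0.873) and -1.99 and -3.76 at day 30, so the falls lay at day 30. The pluripotency call was kept with any 1 sample left out, but its median was -1.60 without IMR90 EV day 12, -1.49 without MRC5 HIF2A day 12, -0.40 without IMR90 EV day 30, -0.59 without MRC5 HIF2A day 30 and -0.52 without IMR90 HIF2A day 30.

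Smaller shifts over both days were medians of 0.38 for fibroblast genes (adjusted p = 0.000869), -0.56 for epithelial genes (0.00908), -0.34 for cell cycle genes (0.0168), 0.37 for the unfolded protein response (0.00705) and 0.13 for interferon-stimulated genes (0.0284). The adjusted p = 0.769, 0.813, 0.813, 0.36 and 0.373 with an estimated correlation, in that order. Over all genes 0 members of these 5 lists passed, and adjusted over the list alone 3, 1, 0, 3 and 2 were higher. Among these were the epithelial DSP at 2.74, S100A4 at 2.55 and the chaperone HSPA5 at 1.52. The pooled cell cycle and epithelial falls average unlike days. At day 12 these 2 lists had medians of 0.50 and 0.05 (camera, adjusted p = 0.109 and 0.248), and at day 30 -1.23 and -1.06. The medians of the cell cycle list without IMR90 EV day 30 (0.31), MRC5 HIF2A day 30 (0.20) and IMR90 HIF2A day 30 (0.12) changed sign, and its call ended without IMR90 HIF2A day 12 (-0.13). Its call was kept at -0.61 without MRC5 EV day 12, -0.99 without IMR90 EV day 12, -0.93 without MRC5 HIF2A day 12 and -0.67 without MRC5 EV day 30. Without MRC5 EV day 30 the fibroblast and interferon medians were 0.84 and 0.21, and the fibroblast median was 0.25 without MRC5 EV day 12, 0.70 without IMR90 EV day 12 and 0.65 without IMR90 HIF2A day 12. Without IMR90 EV day 30 the fibroblast, epithelial, reprogramming and interferon calls also ended (medians 0.16, -0.15, -0.74 and 0.13). The epithelial and reprogramming calls ended without either HIF2A day 30 sample too (-0.25 and -0.77 without MRC5, -0.20 and -0.99 without IMR90). The interferon call ended without MRC5 EV day 12 (0.11) or IMR90 HIF2A day 12 (0.22). Interferon genes also lost their call in 3 other settings (0.14 to 0.41, adjusted p = 0.0569 to 0.0896), and epithelial genes under a filter on all 8 samples (-0.38, adjusted p = 0.67).

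The correlation within arrays was estimated anew with each sample left out. It ran from -0.68 without MRC5 HIF2A day 30 to 0.56 without IMR90 HIF2A day 12, against -0.022 with all samples. The number of genes over both days moved with the samples entered and with that correlation, and the 2 were not separated. The number was 18 without MRC5 EV day 12, 412 without IMR90 EV day 12, 73 without MRC5 HIF2A day 12, 0 without IMR90 HIF2A day 12, 3 without MRC5 EV day 30, 1220 without IMR90 EV day 30, 71 without MRC5 HIF2A day 30 and 34 without IMR90 HIF2A day 30. The direction is that of the labels. In MRC5 at day 30 the coding EPAS1 probe was lower with HIF2A, which cannot decide the label, and the HIF target median of 1.24 went with the label. The split of 25 higher to 2 lower became 585 to 635 without IMR90 EV day 30, 226 to 186 without IMR90 EV day 12 and 164 to 36 with the authors' log2 table, and 56 genes passed without the cell line block.

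From day 12 to day 30 with EV, the course of reprogramming without added HIF2α, genes of the pluripotent state led the genes named. POU5F1 differed by 8.29 ± 0.86, LEFTY2 by 6.76 ± 0.54, the DNA methyltransferase DNMT3B by 6.85 ± 0.85 and the sialomucin PODXL by 6.60 ± 1.45. NANOG differed by 6.20 ± 0.84 and SALL4 by 5.37 ± 0.48, beside 5.71 for DMKN and 5.50 for the junction protein F11R. NLRP7 and DPPA5 were not well above background at day 12 and lay at least 132-fold and 71.6-fold higher at day 30, and LIN28A at least 28.3-fold (fitted difference 4.82). SOX2 differed by 2.82 (adjusted p = 0.074), EPAS1 at its 3′ probe by 0.56 and HIF1A by -0.05. In MRC5 and IMR90 EPAS1 (2.48 and -1.36) and HIF1A (0.17 and -0.27) had opposite signs. TNFSF10, not well above background at day 30, differed by -0.24 ± 0.38 (adjusted p = 0.725). It was 0.01 in MRC5 and -0.48 in IMR90, so no lower bound is given. At day 12, 1 of the 2 EV samples was well above background for LEFTY2, NANOG, DMKN, CDH3 and CXCL6. In the other direction lay MMP1, a collagenase, at -4.31, ADRA1B at -3.80, the pentraxin PTX3 at -3.35 and the pregnancy glycoproteins PSG8 and PSG6 at -3.27 and -2.90. HYI lay at -3.20, the DNA sensor adaptor STING1 at -3.18, the growth factor IGF2 at -3.17, PSORS1C2 at -3.14 and TOX2 at -3.05. By limma 0 genes passed, the smallest adjusted p being 0.0619, while 5278 had an unadjusted p under 0.05. Other settings called 1676 genes with the processed signals, 1372 with the authors' log2 table and 1120 with trend and robust eBayes. They called 578 without the cell line block, 333 without background correction, 17 under a filter on all 8 samples, and 0 in the rest that kept all samples. Without MRC5 EV day 30 the count was 1199. The median of all genes was -0.07 and moved to -0.21 with the processed signals.

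The pluripotency list rose with EV, with a median of 2.36 and 29 of 31 members higher in both lines (camera, adjusted p = 2.7e-16; adjusted p = 0.523 with an estimated correlation; fry 0.0433). Epithelial genes rose, with a median of 1.66, P-cadherin, CDH3, at 4.95 and CDH1, dim at day 12, at least 24.5-fold higher (adjusted p = 1.87e-10; adjusted p = 0.523 with an estimated correlation; fry 0.0433). Reprogramming factors rose, with a median of 3.82 (adjusted p = 1.35e-05; adjusted p = 0.523 with an estimated correlation; fry 0.0433). Over all genes 0 members of the 3 lists passed, and adjusted over the list alone 27, 17 and 5 were higher. Secreted inflammatory genes rose, with a median of 1.25 and the chemokine CXCL6 at 5.98 (adjusted p = 0.0011; adjusted p = 0.904 with an estimated correlation), with 6 higher and 1 lower when adjusted over the list alone. Respiratory chain genes had a median of 0.65 (adjusted p = 0.0125; adjusted p = 0.775 with an estimated correlation), 2 higher and 1 lower when adjusted over the list alone. The p53 targets fell, with a median of -0.65 and CDKN1A, the p21 cell cycle inhibitor, at -2.13 (adjusted p = 0.0139; adjusted p = 0.523 with an estimated correlation), 2 when adjusted over the list alone. In these 3 lists 0 members passed over all genes. Without IMR90 EV day 30 the epithelial median was 1.09, and without MRC5 EV day 30 the respiratory median was 1.27. The inflammatory call ended without MRC5 EV day 30 (median 0.61, adjusted p = 0.0817), the respiratory call without IMR90 EV day 30 (median 0.30, adjusted p = 0.164) and with the authors' log2 table (0.69, adjusted p = 0.0549). The p53 call ended without IMR90 EV day 12 (-0.55, adjusted p = 0.0965) and with the processed signals and the authors' log2 table (-0.62 and -0.64, adjusted p = 0.0782 and 0.0593).

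From day 12 to day 30 in the samples labelled HIF2A, the naming rule gave genes that did not pass. PNOC, a neuropeptide precursor, differed by 5.70 ± 0.65, MGP, a matrix inhibitor of calcification, by 5.40 ± 0.43, MXRA5 by 5.27 ± 0.33, the heparan sulfatase SULF2 by 5.18 ± 0.28 and the matrix protein DPT by 5.05 ± 0.40. In the other direction lay NPTX1, a neuronal pentraxin, at -4.35, TOX2 at -3.72, the troponin TNNT1 at -3.52, DIPK1B at -3.24 and HIP1R at -3.12. POU5F1 differed by 3.99 (adjusted p = 0.174), NANOG by 1.51, LIN28A by 0.83, SOX2 by -0.19, EPAS1 at its 3′ probe by 0.13, HIF1A by -0.89 and TNFSF10 by 1.49 (adjusted p = 0.209). In MRC5 and IMR90, SOX2 (0.15 and -0.52) and HIF1A (-1.87 and 0.10) had opposite signs. The lines also lay apart for POU5F1 (2.36 and 5.62), NANOG (0.44 and 2.58), LIN28A (0.32 and 1.33) and TNFSF10 (0.80 and 2.18). NANOG and LIN28A were well above background in 1 of the 2 samples at day 12. By limma 0 genes passed, the smallest adjusted p being 0.0632 for MXRA5 and SULF2, with 3336 at an unadjusted p under 0.05. Other settings called 362 genes with the processed signals, 254 with the authors' log2 table, 124 with trend and robust eBayes, 55 without the cell line block and 0 to 2 in the rest. The cell cycle list fell, with a median of -1.28 and the cyclin-degrading enzyme UBE2C at -2.30 (camera, adjusted p = 8.07e-06; adjusted p = 0.758 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and the call ended without MRC5 HIF2A day 12 (median -0.50, adjusted p = 0.0921). Glycolysis genes fell, with a median of -0.82 and the phosphofructokinase PFKP at -1.66 (adjusted p = 0.00071; adjusted p = 0.758 with an estimated correlation), 4 when adjusted over the list alone and 0 over all genes.

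Whether the HIF2A effect differed between days was tested as day 30 minus day 12. The difference was -8.32 ± 2.06 for PODXL, -6.63 ± 1.03 for NPPB, -5.48 for DNMT3B, -5.03 for DPPA5 and -4.98 for LEFTY2, so that these lay lower relative to EV at day 30 than at day 12. It was 5.27 for PSORS1C2, 4.88 for PNOC, 4.34 for the lipid kinase PIP5K1C, 4.14 for COXFA4L3 and 3.82 ± 0.26 for PCSK6. At day 12, 0 of 4 samples were well above background for DPPA5, 1 of 4 for LEFTY2 and 0 of the 2 EV samples for PCSK6, so their differences rest partly on dim signals, as do those of PNOC and COXFA4L3 with 1 of the 2 EV samples. Values were 1.73 for TNFSF10, -4.30 for POU5F1, -3.00 for SOX2, -4.68 for NANOG, -3.995 for LIN28A, -0.43 for EPAS1 at its 3′ probe and -0.84 for HIF1A (adjusted p = 0.433 to 0.907). Those of TNFSF10, NANOG and LIN28A rest partly on dim signals too. In EV, TNFSF10 was well above background in 1 of 2 samples at day 12 and 0 of 2 at day 30. At day 12 NANOG was so in 1 of 2 samples of each group, and LIN28A in 0 of 2 EV and 1 of 2 HIF2A samples. By limma 0 genes passed, the smallest adjusted p being 0.331 for PCSK6, with 2077 at an unadjusted p under 0.05. Other settings called 153 with the authors' log2 table, 118 with the processed signals, 7 with trend and robust eBayes and 0 in the rest. Lists that fell had medians of -2.07 for pluripotency (camera, adjusted p = 9.46e-17), -3.50 for reprogramming factors (6.71e-06), -1.56 for epithelial genes (2.41e-10) and -1.72 for the cell cycle (7.21e-08). Others were -0.75 for glycolysis (0.000386), -0.65 for secreted inflammatory genes (0.00734) and -0.53 for the respiratory chain (0.00344). The p53 targets rose, with a median of 0.84 (6.11e-05). In the same order, adjusted p = 0.503, 0.503, 0.529, 0.597, 0.552, 0.724, 0.552 and 0.493 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 17 pluripotency genes, 4 reprogramming factors and 10 epithelial genes were lower, and 0 in the other 5 lists. By fry the 8 lists had 0.152 to 0.63. Calls that were kept moved too. The cell cycle median was -2.85 without MRC5 EV day 30, -0.97 without IMR90 EV day 12, -1.13 without MRC5 HIF2A day 12 and -0.56 without IMR90 EV day 30, and the epithelial median was -2.38 without MRC5 EV day 30. Without IMR90 EV day 30 the epithelial, pluripotency, glycolysis and inflammatory medians were -0.76, -1.19, -0.48 and -1.23. The glycolysis median was -0.48 also without IMR90 EV day 12, and the respiratory median was -0.33 without MRC5 EV day 12 and -0.996 without IMR90 HIF2A day 12. The glycolysis call ended without IMR90 HIF2A day 12 (-0.71). The inflammatory call ended without MRC5 EV day 12 (-0.21), IMR90 HIF2A day 12 (-0.95), MRC5 EV day 30 (-0.12) or MRC5 HIF2A day 30 (-0.27). The respiratory call ended without MRC5 HIF2A day 12 (-0.26) or IMR90 EV day 30 (-0.31) and with the processed signals and the authors' log2 table (-0.45 and -0.46, adjusted p = 0.113 and 0.189).

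The HIF2A effect in IMR90 minus that in MRC5 had an SD of 0.686 over genes, with 3294 at least 2-fold. HIF2A against EV over both days had 0.541 and 1318. The first is less precise, with an SE of 1.41 against 0.56 for EPAS1 at its 3′ probe. The 2 spreads therefore do not compare sizes of effect. The difference in effect between the lines was 2.34 ± 0.29 for the metallothionein MT2A, 2.04 for GAS6, 1.96 for PLPPR2, 1.95 for the urokinase receptor PLAUR and 1.91 for endoglin, ENG. It was -2.94 ± 0.35 for NPTX1, -2.93 for the RNA-binding protein IGF2BP3, -2.66 for the long noncoding RNA MIAT and -2.29 for BNIP3, a mitophagy receptor and HIF target. By limma 0 of 22121 genes passed, the genes above having an adjusted p of 0.775, and 0 passed in every other setting run. With 1 sample left out the range was 0.83 to 3.25 for GAS6, 0.96 to 2.96 for PLPPR2, 0.75 to 3.07 for ENG, -3.48 to -1.09 for BNIP3 and -4.32 to -1.53 for IGF2BP3. The ends nearest 0 came without either HIF2A day 12 sample and the farthest without either HIF2A day 30 sample. The term was 0.06 for EPAS1 at its 3′ probe, -1.19 for HIF1A, 0.27 for TNFSF10, -0.16 for POU5F1, 0.65 for SOX2, -0.55 for NANOG and -0.42 for LIN28A (adjusted p = 0.775 to 0.99). Only 362 had an unadjusted p under 0.05, below the 1106 of chance. The effect was higher in IMR90 for secreted inflammatory genes, by a median of 0.52 (camera, adjusted p = 0.0287), germ layer markers by 0.35 (0.0355), blood cell markers by 0.52 (0.0385) and muscle and fat markers by 0.94 (0.0394). For respiratory chain genes it was lower, with a median of -0.59 (0.0287). All 5 had an adjusted p = 0.952 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Without either EV day 12 sample the inflammatory, blood cell and muscle medians were 1.05, 0.81 and 2.09, and without either HIF2A day 12 sample the respiratory median was -0.23. Without either HIF2A day 30 sample each of the 5 calls ended, with medians of 0.20, 0.56, 0.56, 1.31 and -0.79 in that order. The muscle and fat list changed sign without either EV day 30 sample (-0.22) and lost its call without either HIF2A day 12 sample (0.34) and in 4 other settings (0.55 to 1.08, adjusted p = 0.0531 to 0.137). The inflammatory call ended in 3 other settings (0.58 to 0.72, adjusted p = 0.111 to 0.194), the blood cell call under a filter on all 8 samples (0.62, adjusted p = 0.111) and the germ layer call without a filter (0.16, adjusted p = 0.137). The blood cell call ended also without either EV day 30 sample (0.23) or either HIF2A day 12 sample (0.23). The germ layer call ended without either EV day 12 (0.39) or HIF2A day 12 sample (0.23), and the respiratory and inflammatory calls ended without either EV day 30 sample (-0.32 and 0.03).

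IMR90 against MRC5, which cannot be told apart from Cy5 against Cy3, gave 2 of 22121 genes in limma. CTAG1A, a cancer-testis antigen, was higher in IMR90 by 4.95 ± 0.14 (adjusted p = 0.0114) and PLAC4 by 2.70 ± 0.11 (adjusted p = 0.0388), in 4 of 4 pairs each. Differences that did not pass were 2.80 for the glutathione transferase GSTT2, 2.08 for the mucin MUC4, and 1.70 for SERPINB9. In the other direction lay -2.90 for ACTL8, -2.44 for GSTT1, -2.34 for the lens protein CRYBB2, -1.89 for ELP5 and -1.50 for HLA-DPA1. POU5F1 differed by 1.40, SOX2 by 1.30, NANOG by 1.12, LIN28A by 0.65, TNFSF10 by 0.22, EPAS1 at its 3′ probe by 0.17 and HIF1A by 0.03, none of which passed. At an unadjusted p under 0.05 there were 665 genes, below the 1106 of chance. With any 1 sample left out 0 passed, and 18 passed with the processed signals, 9 higher and 9 lower. Pluripotency genes were higher in IMR90, by a median of 0.45 (camera, adjusted p = 1.49e-08), as were epithelial genes by 0.40 (6.93e-06) and reprogramming factors by 0.88 (0.00928), while fibroblast genes (median -0.37, 0.00771) and p53 targets (median -0.15, 0.021) were lower, with adjusted p = 0.843 for all 5 with an estimated correlation. In these lists 0 members passed over all genes and 1 epithelial gene adjusted over the list alone. The pluripotency median was -0.06 in EV day 12, 0.04 in HIF2A day 12, 1.52 in EV day 30 and 0.16 in HIF2A day 30, so the difference lay mostly in 1 pair. Without a day 30 EV sample the fibroblast, p53 and reprogramming calls ended (medians -0.02, -0.005 and 0.39), and the epithelial and pluripotency medians were 0.13 and 0.11. Without a day 12 EV sample the fibroblast and epithelial medians were -0.63 and 0.62. Without a HIF2A day 12 sample the fibroblast and p53 calls ended (-0.21 each). Without a filter on dim probes the fibroblast and reprogramming calls ended (adjusted p = 0.0551 and 0.0538) at unchanged medians of -0.37 and 0.88, and the p53 call ended in 3 other settings (-0.16 to -0.15, adjusted p = 0.0654 to 0.239).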

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

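Both tests of explanations for the lower pluripotency genes at day 30, swapped labels and a mixture of cells, were chosen after the result was seen. The results in this part are gene lists whose HIF2A effect differed between the days or between the lines by a test of the difference itself. No group held 4 samples or more, so no single sample was tested for lying far from the others.

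Between day 12 and day 30 the HIF2A effect differed in 8 lists, by the samples' labels. The median difference was -2.07 for pluripotency genes, -3.50 for reprogramming factors, -1.56 for epithelial genes, -1.72 for cell cycle genes, -0.75 for glycolysis genes, -0.65 for secreted inflammatory genes, -0.53 for respiratory chain genes and 0.84 for p53 targets. All 8 lost their call when the correlation between genes was estimated (adjusted p = 0.493 to 0.724). Between the lines, IMR90 minus MRC5, it differed by a median of 0.52 for secreted inflammatory genes, -0.59 for respiratory chain genes, 0.35 for germ layer markers, 0.52 for blood cell markers and 0.94 for muscle and fat markers, all with an adjusted p = 0.952 with an estimated correlation. The list of HIF targets was not among these 13, at a median of -0.08 between days (adjusted p = 0.439) and -0.01 between lines (adjusted p = 0.763).

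The lower pluripotency genes in the day 30 samples labelled HIF2A were weighed against 2 technical explanations. If EV and HIF2A labels had been swapped at day 30, HIF targets should lie below 0 there, and their medians were 1.24 in MRC5 and 1.70 in IMR90, which argues against a swap. The coding EPAS1 probe was lower with HIF2A in MRC5, at -0.71, and higher in IMR90, at 0.88. The 3′ probe differed by -2.74 and -0.81 in these pairs. The coding probe may read the cells' own EPAS1 too, so its sign cannot decide the label. A lower share of pluripotent cells in a mixed sample stays open, since 51.5% of 33 fibroblast genes were higher in both lines, with medians of 0.11 in MRC5 and 1.16 in IMR90. Among the 19 pluripotency genes measured in these groups the medians were -1.83 and -3.86. An effect of HIF2α on the cells cannot be told apart from such a mixture, because RNA was taken from whole cultures, nor from the array, since each group had its own.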

How the results depend on the processing

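Alternatives chosen after the data had been seen were the other EPAS1 probe and leaving out both samples least like the others. Of the named genes past the threshold, 28 in all, each kept its direction in every setting that tested it other than leaving out 1 sample, and all 45 called lists did so under the other signal settings. All 15 genes of day 30 still passed without background correction, with quantile normalization, with the processed signals, without a filter, with trend and robust eBayes, without the cell line block and with the array block. In the others 14 did with the authors' table, 13 with the mean of probes and 4 under a filter on all 8 samples. That filter left untested the genes with no probe well above background in every sample. Of the 28 named results it tested 15, and all 15 still passed. Of the 27 genes over both days, 9 passed without a filter, 22 under a filter on all 8 samples and 25 or more in the others that kept all samples. Of the 45 list calls fry kept 5 and camera with an estimated correlation 0. The causes of the changes below were not tested.

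Counts of genes are given for day 12, day 30, day with EV and both days of virus, against 0, 15, 0 and 27. They were 7, 127, 333 and 44 without background correction, 94, 1239, 1676 and 220 with the processed signals, 87, 1025, 1372 and 200 with the authors' log2 table, and 26, 1043, 1120 and 71 with trend and robust eBayes. A filter on all 8 samples gave 1, 60, 17 and 53. Day 30 had 35 genes with quantile normalization. Without a filter day 30 had 23 genes and both days 9, and with the mean of a gene's probes day 12 had 4 and day 30 had 37. Without the cell line block, that is without pairing, the counts were 14, 124, 578 and 56, with 55 for day with HIF2A, and with the array as a random block day 12 had 5 and day 30 had 48. Day with HIF2A gave 362 with the processed signals, 254 with the authors' table, 124 with trend and robust eBayes, 2 without a filter, 2 under a filter on all 8 samples and 1 with the mean of probes, against 0. The difference between days gave 118, 153 and 7 in the first 3 of these, against 0. IMR90 against MRC5 gave 1 gene without background correction, 0 with quantile normalization, 18 with the processed signals, 11 with the authors' table and 1 with trend and robust eBayes, against 2.

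With both samples least like the others left out, day 30 and the line comparison had 0 genes in limma (4794 and 933 at an unadjusted p under 0.05). SOX2 at day 12 was 0.12, and list medians turned to -0.11 for fibroblast genes at day 30, -0.0049 for epithelial genes between lines and 0.26 for fibroblast genes between lines, which passed the other way (adjusted p = 0.0103). There the comparison over both days was not run because the correlation within arrays could not be estimated, and the line by virus comparison was not run. LIN28A at day 12 turned to 0.0163 without background correction, and NANOG to 0.0307 with quantile normalization and 0.0855 with the processed signals. The coding probe turned EPAS1 to 1.26 at day 12 and 0.0851 at day 30.

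Leaving out each sample in turn, where a lone sample was assumed to vary like the other groups, gave 0 to 632 genes at day 30, 0 to 1199 for day with EV, 0 to 1220 over both days and 0 between lines. Day 30 and day with EV were highest without MRC5 EV day 30 and both days without IMR90 EV day 30. In that last fit the correlation within arrays was estimated at -0.61, against -0.022 with all samples. At day 12 POU5F1 ran from -1.51 to 0.77, SOX2 from -1.13 to 0.21, NANOG from -0.92 to 0.87, LIN28A from -0.64 to 0.53 and HIF1A from -1.14 to 0.97. Medians ran from -0.0866 to 1.22 for fibroblast genes at day 30, from -0.99 to 0.31 for cell cycle genes over both days and from -0.22 to 2.09 for muscle and fat markers between lines. Signal over background, with a median of 2.12 to 4.01 per sample, limits genes such as LIN28A at day 12, which lay near the background.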

Other observations

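Chosen only after the data had been seen were the limma test of the coding EPAS1 probe, the tests at the glycolysis list's median brightness and the look at which split of the samples called the most genes.

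The cell cycle list followed the samples as much as the groups. IMR90 minus MRC5 had a median of -1.26 in EV day 12, -0.87 in HIF2A day 12, 1.53 in EV day 30 and 0.11 in HIF2A day 30. The lines differed most, over all genes, in HIF2A day 12 and EV day 30 (SD 0.829 and 0.788) and least in HIF2A day 30 (0.259), and the differences of those first 2 groups correlated at r = -0.384. Lists of endothelial, germ layer, blood cell, and muscle and fat markers were not called for HIF2A against EV at day 12, at day 30 or over both days. Over both days their medians were -0.14 for endothelial genes (adjusted p = 0.383), -0.14 for germ layer markers (0.722), -0.09 for blood cell markers (0.367) and -0.26 for muscle and fat markers (0.383). The death receptor list had a median of 0.23 over both days (adjusted p = 0.179), with 2 members higher, among them TNFSF10, and 2 lower when adjusted over the list alone.

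Chance was not excluded for the counts of genes over both days or between lines. With the correlation within arrays estimated from 1 in 5 genes, the real split of the 8 samples over both days called 26 genes, 2 of 33 splits, the real included, called as many, and the highest other called 2860. Of the 17 splits with 2 samples of each line on either side, 2 called as many, with the same highest other. For IMR90 against MRC5 the real split called 2 genes, 3 of 32, the real included, called as many, and the highest other called 1854. Of the 8 splits that parted the samples of all 4 pairs, 1, the real, called as many and the highest other called 0. With only 17 and 8 splits a share under 0.05 was out of reach, so these narrower sets could not exclude chance. Another 2 and 3 splits could not be fitted. The split that called 2860 genes set MRC5 HIF2A day 12, IMR90 EV day 30 and both HIF2A day 30 samples against the rest, so it held 3 of the 4 samples labelled HIF2A and overlapped with the groups.

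Noise of single spots or probes was tested on other probes of the genes past the threshold. At day 30, 7 other probes of 6 genes moved in the called direction by a median of 2.00, beside 3.46 for the called probes. Over both days, 18 of 18 other probes of 11 genes did so by a median of 2.66, beside 4.11. Both argue against probe noise as the source of these calls, for the genes that have other probes.

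HIF target genes rose over both days, with a median of 1.47 (camera, adjusted p = 2e-20; adjusted p = 0.089 with an estimated correlation), and glycolysis genes were not called, with a median of -0.07. The difference between the lists was not itself tested. The glycolysis median over both days lay between 0.14 at day 12 (adjusted p = 0.0949) and -0.49 at day 30 (adjusted p = 0.0287; adjusted p = 0.495 with an estimated correlation). The change between days was -0.75 (adjusted p = 0.000386; adjusted p = 0.552 with an estimated correlation). Compression of bright signals was tested, since glycolysis genes are bright, and above the list's lower quartile of brightness, a log2 level of 9.47, the SD of the change was 1.46 times that of dimmer genes. From the list's median brightness of 13.5 up it was 0.945 times, 4 HIF targets had a median of 2.12, and the 11 glycolysis genes dimmer than that had a median of -0.41. Among 4 other signal settings the highest ratio of the glycolysis median to the HIF target median was 0.0132. The SD ratios cannot decide on compression, because dimmer genes lie nearer the background, where the offset of background correction damps changes. The 17 HIF targets above 9.47 had a median of 2.04, but from 13.5 up only 4 were left. These values argue against compression only for the 11 dimmer glycolysis genes. The processed signals and the authors' log2 table ranked probes almost alike, so they are not separate checks. For the settings run, the low ratios of the list medians argue against background correction and normalization. The cause of the difference was left open.

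The EPAS1 probes differed by 2.23 over both days in their change, and 0.143% of 4204 pairs of probes of other genes (6 pairs) differed as much, with a median of 0.189. That argues against spot or probe noise. The coding probe moved above the 3′ probe in 4 of 4 pairs, by 2.00 and 3.20 at day 12 and 2.02 and 1.70 at day 30 in MRC5 and IMR90. By itself the coding probe was lower in the MRC5 day 30 sample labelled HIF2A (-0.71) and differed by 0.09 ± 0.75 at day 30 in limma (adjusted p = 0.977). No biological explanation of the gap was tested.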
